A study of Homo sapiens with 6 samples.

How the data were processed

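RNA from 6 samples of the cell line HEK 293FT, 3 titled HEK 293FTGFP cells and marked Vec (GFP group) and 3 titled HEK 293FTGFP-CTRB1 cells (CTRB1 group), was sequenced as paired-end libraries on an Illumina instrument, per the labels. One deposited table with all 6 samples was analysed. Its per-sample columns hold read counts per gene, per the file headers, and the values are whole numbers that the authors did not normalize. The deposited FPKM values and the deposited TPM values are the authors' own normalized expression per gene, per the file headers. The FPKM columns are proportional to the TPM columns within a library. The deposited FPKM is not the count divided by 1 fixed length per gene: among 8819 genes with over 500 counts in every library, the ratio of count to FPKM differed between libraries by more than 1.1-fold for 21% of genes, after division by each library's median. The authors' deposited comparison gives a log2 fold change, positive where the CTRB1 group is higher, and a p-value with an adjusted p-value per gene, with no tool named in the sources used here.

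The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.2.1 and HTSeq 0.6.1 without stating their roles, and they name the mouse build GRCm38.p5. All 20345 gene identifiers in the table are human Ensembl identifiers, and 19446 of them were found in a table of gene names. The build behind the coordinates is not given in the sources used here. Of 19498 nuclear genes shared with the GENCODE v29 annotation of GRCh38, 115 had the same start, and the last gene of chromosome 1 ends at 249214145 in the table and at 248937043 in GRCh38, so coordinates are printed as the table gives them and were not combined with GRCh38. GENCODE v29 was used only for transcript sequences, GC content and transcript length. Whether strand was used in counting is not stated, so overlapping genes on opposite strands cannot be separated. Spreadsheet conversion had turned 29 gene names into dates, and a second name column of the table was used for them. Only protein-coding genes are in the table, 2370 of which had no count in any library. The table carries no pathway annotation, so the term enrichment foreseen in the design was not run.

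The design foresaw limma on FPKM unless the table held counts. It held counts, so edgeR 4.0.16 was used on them in R 4.3.3, with TMM factors (0.9964 to 1.0036), and genes were kept when FPKM was at least 1 in at least 3 of the 6 libraries, which left 11961. Both groups entered 1 model without covariates, the quasi-likelihood F test gave p-values, and the Benjamini-Hochberg adjustment ran over all genes tested with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values use TMM-adjusted library sizes and are given as mean ± SD over 3 libraries. For CTRB1 and CTRB2, pooled ratios have exact conditional 95% intervals, and the share of CTRB2 has exact binomial 95% intervals. These, like the floor of 3 counts, cover counting error only. Their coding sequences of 789 bases were compared from GENCODE v29 transcripts.

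Gene lists, 35 in all, were written before the data were examined. They cover the unfolded protein response, integrated stress response, heat shock, cell cycle, p53 targets, apoptosis, interferon, NF-kB, immediate early, YAP/TAZ, matrix, junction, mesenchymal, protease inhibitor, protease, coagulation, acinar, secretory transport, lysosome, cholesterol, glycolysis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, ribosome biogenesis, cell competition, TGF-beta, Wnt, Notch, antigen presentation and HEK293 neuronal genes, and markers of fibroblasts, blood, endothelium and keratinocytes. Lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists tested; camera with an estimated correlation and fry were run beside it. Genes named in the text follow a rule that was also fixed in advance: CTRB1 and CTRB2; the 10 largest rises and the 10 largest falls among called genes with an own symbol, a mean FPKM of at least 1 in the higher group and no overlap between the groups; and up to 4 called members of each list by smallest adjusted p, or the 2 with the smallest p where none was called. Not every gene that the rule selects is named in the text. ATF4, DDIT3, ATF5, HSP90AA1, HSP90AB1, CDKN1A, MDM2, BHLHA15 and AMY2B were named as list members after their values were seen.

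Total counts were 52571457, 64859210 and 159616285 in the GFP libraries and 31557364, 32522018 and 27514767 in the CTRB1 libraries. The tests were run first on simulated counts for the same genes and libraries with 50 genes changed at each of 4 fold sizes. Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no expression filter, a mean FPKM of at least 5, the replicate number as a block, leaving out each library, and limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 5, median-of-ratios scaling, quantile normalization, rescaling of FPKM to a common sum, and without trend or robust moderation. Running limma on log2(FPKM + 1) beside edgeR, thinning to 27514767 counts per library, thinning of GFP replicate 3, an offset for GC content and length (loess, span 0.4, for the 98.6% of tested genes with a GC value) and the p53 list without SESN2 were added after the data were seen. The other limma settings were fixed in advance and were run on that fit. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 was used for reading the table, sequence comparison and figures.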

Results

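RNA was sequenced from HEK 293FT cells, a human embryonic kidney line that carries the SV40 large T antigen, in 2 groups of 3 libraries. The titles name the first group HEK 293FTGFP cells and mark it Vec, a term they do not spell out, and they name the second HEK 293FTGFP-CTRB1 cells; the groups are called GFP cells, for green fluorescent protein, and CTRB1 cells here. CTRB1 encodes chymotrypsinogen B1, the inactive precursor of a digestive serine protease that pancreatic acinar cells secrete. The title of the series places CTRB1 in the defence of epithelium and stroma against tumour cells, and the comparison asks which transcripts differ between cells with and without it. The GFP libraries held 52571457, 64859210 and 159616285 counts over 20345 protein-coding genes, and the CTRB1 libraries held 31557364, 32522018 and 27514767. Every GFP library was therefore deeper than every CTRB1 library, and a floor of 3 counts corresponded to 0.0188 to 0.109 CPM (counts scaled to library size), counting error only. Mitochondrially encoded genes took 5.3 to 5.81% of the counts of a library. Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 5.86 to 7.80, and libraries of different groups differed by 27.1 to 41.4. The labels do not say whether the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

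CTRB1 transcripts were abundant in all 3 CTRB1 libraries and close to the floor in all 3 GFP libraries. CTRB1 (ENSG00000168925; chromosome 16, positions 75252898 to 75258822 in the coordinates of the table, whose genome build is not named) had 22749, 22161 and 19345 counts in the CTRB1 libraries and 1, 0 and 5 in the GFP libraries. Its FPKM was 699 ± 22.5 (SD, n = 3) against 0.016 ± 0.014 (SD, n = 3). Pooled over each group and scaled by depth, the ratio was 32400, with a 95% interval of 14900 to 88300 that covers counting error only. The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 4.91e-16, and an exact two-sided permutation test of the group means gave p = 0.1, the smallest value that 3 against 3 libraries allow. CTRB2 (ENSG00000168928; chromosome 16, positions 75237994 to 75241083), the neighbouring chymotrypsinogen gene, had 7196, 7065 and 6073 counts in the CTRB1 libraries and 3, 0 and 1 in the GFP libraries, a pooled ratio of 15400 (95% counting interval 6000 to 56400; edgeR adjusted p = 8.52e-15). With so few counts in the GFP libraries the size of both changes is loosely set: the edgeR log2 change of CTRB1 was 14.85, and 15.89 without GFP replicate 3, and that of CTRB2 was 13.71, with 12.92 without GFP replicate 3 and 15.07 without GFP replicate 1. The limma fits, which add a pseudocount to FPKM, gave 7.13 to 12.57 for CTRB1 and 5.42 to 10.94 for CTRB2. The coding sequences of both genes are 96.7% identical, and 67.5% of the 150-base windows of one occur unchanged in the other, so the division of reads between them is uncertain. CTRB2 took 24.03%, 24.17% and 23.89% of the counts of both genes in the 3 CTRB1 libraries, with exact binomial 95% intervals within 23.37 to 24.67%.

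Beyond CTRB1, expression shifted across much of the transcriptome, mostly by small amounts. Genes of the integrated stress response, such as ASNS and SLC7A11, rose, while cytosolic heat shock genes and genes of cholesterol synthesis fell. Of 11961 genes tested, 4479 (37.4%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2221 of them higher and 2258 lower in CTRB1 cells. The median change of these genes was 1.146-fold, and 4201 of them changed by less than 0.5 on the log2 scale. A log2 change of at least 1 was seen in 29 higher and 13 lower genes. All 3 libraries of one group lay above all 3 of the other for 5979 genes (50% of those tested, where chance gives 10%). On simulated counts for the same 11961 genes and 6 libraries, the test recovered 40% of genes changed by 1.2-fold, 86% of those changed by 1.5-fold and 100% of those changed by 2-fold, with 8 false calls among 171. The simulation changed only 50 genes at each of 4 fold sizes, far fewer than were called in the data. The adjusted threshold depends on that number, so these shares do not carry over directly. A limma fit of log2(FPKM + 1), added as an alternative after the data were seen, called 1292 genes higher and 1976 lower. Of its calls 39.5% were higher, against 49.6% here. With FPKM rescaled by median of ratios, limma called 1529 higher and 1728 lower, a share of 46.9%. The share was 46.4% with quantile normalization and 41.6% with FPKM rescaled to a common sum, so it varied with the scaling of FPKM.

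**Figure D1:**
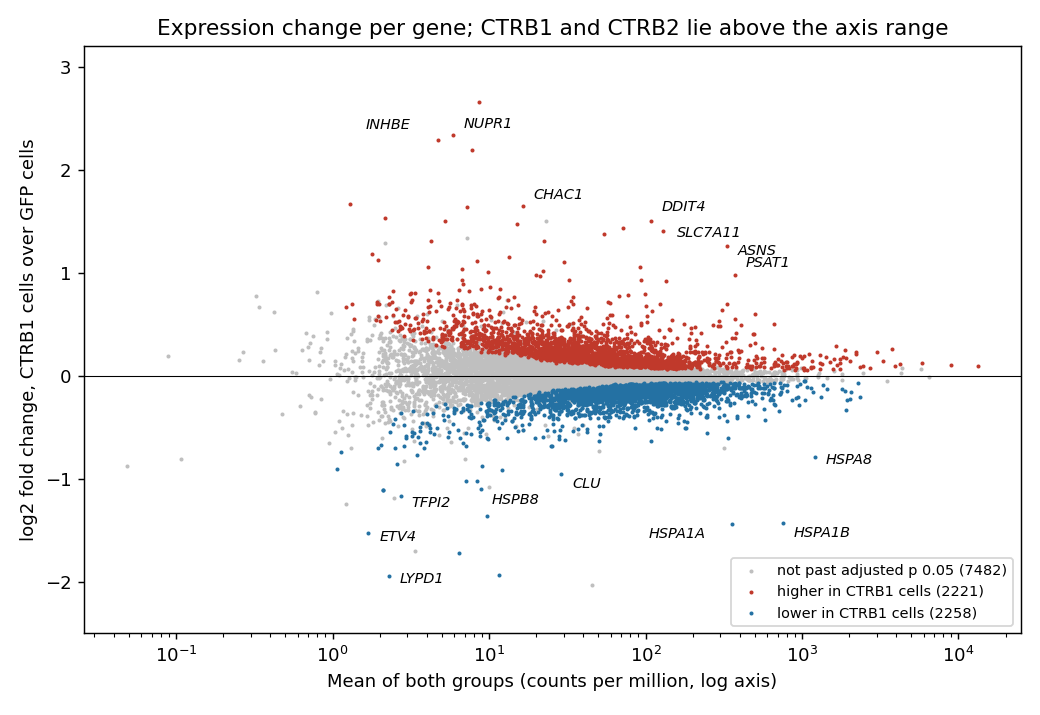
Each point is 1 of the 11961 genes tested, with the mean of both groups in CPM on a log axis (x) and the log2 fold change of CTRB1 cells over GFP cells (y). Red marks the 2221 genes that were higher and blue the 2258 that were lower at an edgeR adjusted p under 0.05. CTRB1 and CTRB2 lie above the range shown, NUPR1 and INHBE have the largest rises among the labelled genes, and most coloured points lie within 0.5 of 0.

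Among the genes that rose most, NUPR1, a stress-induced chromatin protein gene, rose by 2.33 ± 0.124 on the log2 scale (SE; edgeR adjusted p = 4e-07). INHBE, which encodes an inhibin beta subunit, rose by 2.29 ± 0.128 (SE; edgeR adjusted p = 6.04e-07). CHAC1, a glutathione-degrading enzyme gene, went from 7.96 to 25.0 CPM (log2 change 1.65), and ADM2, a peptide hormone gene, from 3.49 to 10.9 CPM (log2 change 1.64). DDIT4, an inhibitor of mTORC1 signalling, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose 2.82-fold and 2.69-fold, with edgeR adjusted p of 2.29e-11 and 8.73e-10. TNMD (log2 change 1.66) and SAPCD1 (2.84-fold higher) stayed below 10 CPM in both groups, and SAPCD1 overlaps MSH5. RPS10-NUDT3, a readthrough gene that shares exons with RPS10 and NUDT3, had a log2 change of 1.53 ± 0.449 (SE; edgeR adjusted p = 0.0209). Its log2 change was 2.40 without GFP replicate 3 and 1.19 without GFP replicate 1, and its call was lost without GFP replicate 2 (edgeR adjusted p = 0.0643), without CTRB1 replicate 1 (edgeR adjusted p = 0.0923), with DESeq2 (adjusted p = 0.0604) and with limma on log2(FPKM + 1) (adjusted p = 0.0842).

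Among the genes that fell most, LYPD1 dropped from 3.64 to 0.949 CPM, 3.85-fold lower (log2 change -1.95 ± 0.18, SE; edgeR adjusted p = 2.07e-05). ETV4, an ETS family transcription factor gene, was 2.89-fold lower (log2 change -1.53; edgeR adjusted p = 0.000648). The inducible HSP70 genes HSPA1A and HSPA1B were 2.71-fold and 2.69-fold lower. TFPI2, a serine protease inhibitor gene, was 2.25-fold lower (log2 change -1.17), at 1.68 CPM in CTRB1 cells. HSPB8, a small heat shock protein gene, had a log2 change of -1.10, and CLU, the gene of the secreted chaperone clusterin, went from 38.2 to 19.7 CPM (log2 change -0.95). MYOF (log2 change -0.92) and PPP1R1C (log2 change -0.91) completed the list together with JSRP1 (log2 change -1.11), which overlaps OAZ1. The edgeR adjusted p of JSRP1 was 0.0108, and 0.0506 without GFP replicate 3. LYPD1, ETV4 and TFPI2 also overlap other genes (GPR39, DHX8 and GNGT1), and since no source says whether counting used strand, reads of such pairs may not be fully separated.

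Genes of the integrated stress response, which ATF4 activates when eIF2alpha is phosphorylated, rose together. Of 22 measured members, 21 were higher and 1 was lower, with the same counts adjusted over the list alone, and the median log2 change was 0.645 (camera adjusted p = 6.42e-97; adjusted p = 0.000966 with an estimated correlation). ASNS, the asparagine synthetase gene (ENSG00000070669; chromosome 7, positions 97481430 to 97501854), went from 195 ± 0.956 to 465 ± 4.38 CPM (SD, n = 3 each), 2.39-fold higher, with an edgeR adjusted p of 2.29e-11. SLC7A11, the cystine transporter gene, rose 2.64-fold and PSAT1, of serine synthesis, rose 1.97-fold (edgeR adjusted p = 1.47e-10 and 8.73e-10). ATF4 itself rose by 0.50 and DDIT3, which encodes CHOP, by 0.50 on the log2 scale. The member that fell was ATF5, a related transcription factor gene (log2 change -0.41).

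Cytosolic heat shock genes moved the other way. All 16 members of the list were lower in CTRB1 cells, also when adjusted over the list alone, with a median log2 change of -0.321 (camera adjusted p = 2.93e-52; adjusted p = 0.00116 with an estimated correlation). HSPA1B (ENSG00000204388; chromosome 6, positions 31795512 to 31798031) fell from 1099 ± 12.7 to 409 ± 10.1 CPM (SD, n = 3 each; edgeR adjusted p = 1.27e-11), and HSPA1A (chromosome 6, positions 31783291 to 31785723) fell from 520 ± 9.75 to 192 ± 6.14 CPM (SD, n = 3 each; edgeR adjusted p = 6.16e-11). Both genes are near-identical copies, so how reads were divided between them is uncertain. HSPA8, the constitutive HSP70 gene, was 1.73-fold lower and HSPH1, an HSP110 gene, 1.47-fold lower (edgeR adjusted p = 1.39e-08 and 5.05e-08). The HSP90 genes HSP90AA1 and HSP90AB1 had log2 changes of -0.34 and -0.23.

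**Figure D2:**
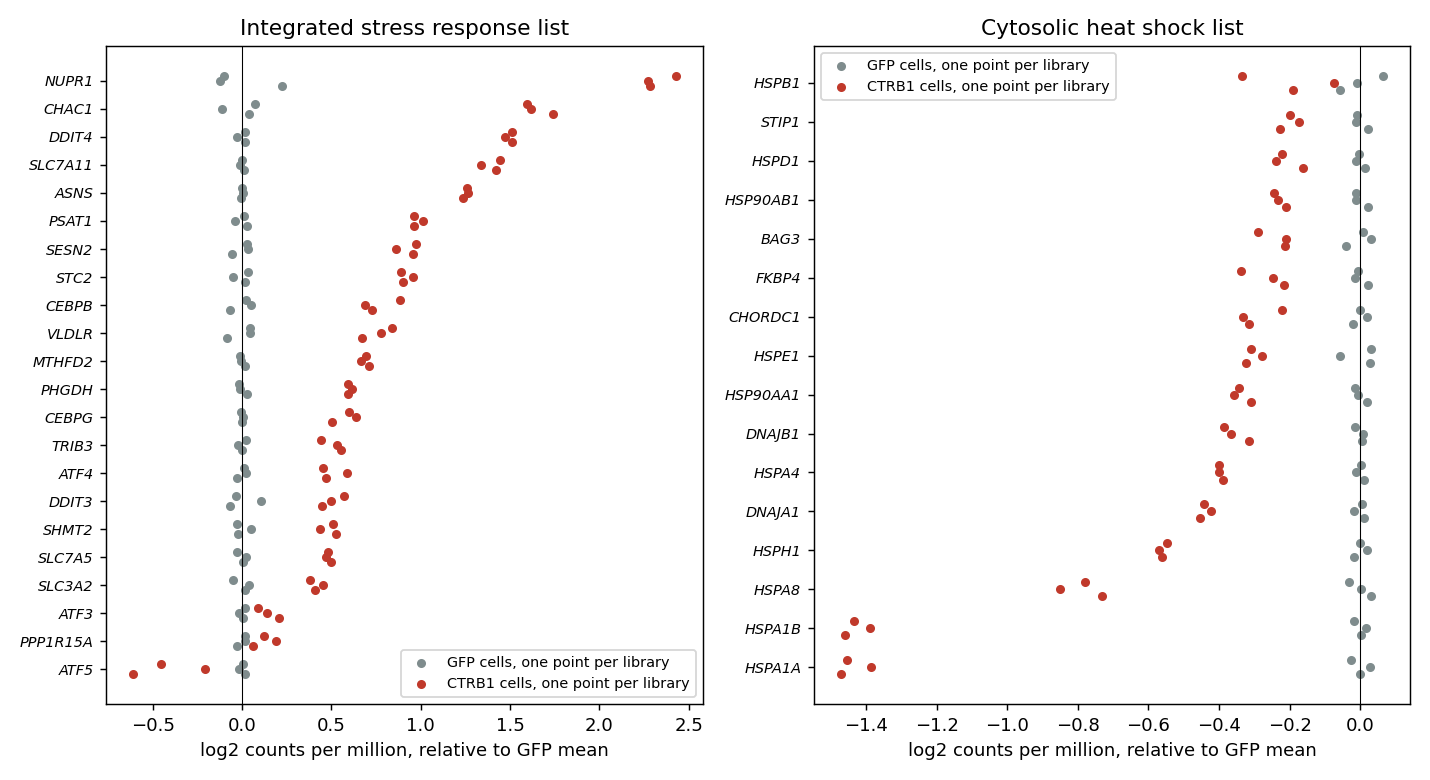
Each point is 1 library, drawn as log2 CPM relative to the mean of the 3 GFP libraries (x), for every measured gene (y) of the integrated stress response list (left, 22 genes) and the cytosolic heat shock list (right, 16 genes). Red points are CTRB1 cells and grey points are GFP cells. Of the 22 genes on the left, 21 were higher in CTRB1 cells and ATF5 was lower, and all 16 genes on the right were lower.

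The lists of cholesterol synthesis, ribosome biogenesis and the lysosome were lower by smaller amounts, the last without a call at an estimated correlation. Of 24 genes of cholesterol synthesis, 18 were lower and 2 higher (20 lower and 2 higher adjusted over the list alone), with a median log2 change of -0.238 (camera adjusted p = 5.19e-12; adjusted p = 0.038 with an estimated correlation). IDI1, HMGCS1 and INSIG1 had log2 changes of -0.44, -0.40 and -0.45. Of 30 MYC target and ribosome biogenesis genes, 22 were lower and 1 higher (23 and 1 adjusted over the list alone; median -0.124; camera adjusted p = 3.05e-07; adjusted p = 0.043 with an estimated correlation), among them NOP16 (-0.39), UTP20 (-0.30) and PES1 (-0.27). The higher member was MYC (log2 change 0.09). Of 34 autophagy and lysosome genes, 20 were lower and 1 higher (21 and 1 adjusted over the list alone; median -0.133; camera adjusted p = 0.000154), a call that was lost with an adjusted p = 0.0933 with an estimated correlation. In that list NEU1, the lysosomal sialidase gene, was 1.55-fold lower, SQSTM1, an autophagy receptor gene, 1.33-fold lower, and LAMP1, a lysosomal membrane protein gene, 1.29-fold lower (edgeR adjusted p = 6.34e-06, 2.41e-05 and 6.34e-06).

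Most ribosomal protein genes rose slightly and 11 of 20 immediate early genes fell, but neither list passed with an estimated correlation. Of 51 cytosolic ribosomal protein genes, 42 were higher and 1 lower (44 and 1 adjusted over the list alone), with a median log2 change of 0.098 (camera adjusted p = 7.44e-09), and the call was lost with an adjusted p = 0.522 with an estimated correlation. RPL13A and RPL3 rose 1.19-fold and 1.17-fold (edgeR adjusted p = 1.29e-06 and 1.82e-06). Of 20 immediate early genes, which respond within minutes to growth factors and stress, 11 were lower and 3 higher (12 and 3 adjusted over the list alone; median -0.334; camera adjusted p = 5.48e-05; adjusted p = 0.291 with an estimated correlation). FOS fell from 61.4 ± 2.05 to 41.5 ± 2.06 CPM (SD, n = 3 each), and IER2, EGR1 and JUN had log2 changes of -0.51, -0.46 and -0.41, with edgeR adjusted p of 7.09e-06 for FOS, 1.32e-06 for IER2, 7.1e-06 for EGR1 and 3.98e-06 for JUN.

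Some p53 target genes rose. Of 23 measured, 11 were higher and 1 lower (14 and 1 adjusted over the list alone; median 0.177; camera adjusted p = 0.00383; adjusted p = 0.123 with an estimated correlation). SESN2, an inhibitor of mTORC1 that the integrated stress response list also holds, rose by 0.93 on the log2 scale, BBC3, which encodes the BH3-only protein PUMA, by 0.62, DDB2, of DNA repair, by 0.49 and TP53INP1 by 0.44 (edgeR adjusted p = 3.55e-08, 0.00015, 0.00104 and 0.00207). Without SESN2 the median log2 change was 0.1763, against 0.1766 with it, but the list did not pass (camera adjusted p = 0.109). CDKN1A and MDM2, the textbook p53 targets, had log2 changes of 0.18 and 0.04 and did not pass over all genes tested (edgeR adjusted p = 0.0754 and 0.184), while CDKN1A is among the 14 adjusted over the list alone.

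The list of the unfolded protein response of the endoplasmic reticulum did not pass (camera adjusted p = 0.677). Of its 25 members, 7 were higher and 6 lower (8 and 6 adjusted over the list alone), with a median log2 change of 0.001. XBP1 and HERPUD1 rose by 0.37 and 0.34 on the log2 scale (edgeR adjusted p = 1.12e-05 and 3.54e-06), while the chaperone genes CALR and HSPA5 had log2 changes of -0.22 and -0.11 (edgeR adjusted p = 2.84e-05 and 0.000679). Among 40 genes of secretory pathway transport, 8 were higher and 13 lower (camera adjusted p = 0.709), with SEC63 at 0.23 and SAR1A at -0.26. Apoptosis regulators were divided, with 4 higher and 7 lower of 25 (camera adjusted p = 0.398): HRK, a BH3-only gene, rose 1.70-fold, and MCL1, an anti-apoptotic gene, was 1.30-fold lower (edgeR adjusted p = 2.84e-05 and 8.36e-07). Cell cycle genes were divided evenly, with 12 higher and 12 lower of 35 (camera adjusted p = 0.924), among them TOP2A (log2 change 0.24) and RRM2 (log2 change -0.23).

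Protease-related lists did not pass the set test, although single members moved. Of 18 measured members of the protease inhibitor list, 2 were higher and 8 lower (camera adjusted p = 0.401). SERPINF1 rose 1.63-fold (edgeR adjusted p = 4.05e-07), and SERPINH1 and TIMP1 had log2 changes of -0.34 and -0.33. Whether each member of the list, these serpins included, inhibits a protease was not tested here. Of 20 secreted and membrane proteases, 3 were higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.924), with PRSS23 at -0.49 and ADAMTS1 at -0.40. Of 10 genes of protease-activated receptors and coagulation, 1 was higher (0 adjusted over the list alone; camera adjusted p = 0.924), namely MET, with a log2 change of 0.11 and an edgeR adjusted p of 0.0469 that rose to 0.161 without CTRB1 replicate 1, 0.0966 without GFP replicate 1, 0.104 without GFP replicate 2 and 0.109 without GFP replicate 3. Among 31 pancreatic acinar genes in the table only 3 passed the expression filter, too few for a set test. They were CTRB2, BHLHA15 (log2 change 0.05; edgeR adjusted p = 0.912) and AMY2B (log2 change -0.36; edgeR adjusted p = 0.162).

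Metabolic lists were mixed. Of 32 glycolysis and hypoxia genes, 7 were higher and 12 lower (camera adjusted p = 0.317). VEGFA, the vascular endothelial growth factor gene, rose 1.71-fold (edgeR adjusted p = 6.65e-07), while the glycolytic enzyme genes PGAM1, PKM and LDHA had log2 changes of -0.29, -0.28 and -0.24. Of 40 nuclear genes of oxidative phosphorylation, 3 were higher and 6 lower (camera adjusted p = 0.576). ATP5MC3, with a log2 change of -0.17, was higher by 0.10 in the limma fit of log2(FPKM + 1), so its direction depends on the unit. Of 13 mitochondrially encoded genes, 5 were higher (camera adjusted p = 0.317). That list passed without CTRB1 replicate 1 (camera adjusted p = 0.0156), and its median changed sign, to -0.01, under quantile normalization.

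Signalling and matrix lists did not pass either. Of 17 YAP/TAZ target genes, 2 were higher and 8 lower (camera adjusted p = 0.298), with AJUBA at 0.52 and FJX1 at -0.52. The list passed as lower in every limma fit of FPKM, with a camera adjusted p of 0.0295 for log2(FPKM + 1). That value ranged from 0.0038 with quantile normalization to 0.0483 with a pseudocount of 5. With fry the list also passed as lower (adjusted p = 0.000366). Of 18 interferon response genes, 7 were higher and 3 lower (camera adjusted p = 0.156), with IFIT2 at 0.45. Of 7 measured NF-kB and inflammatory genes, 2 were higher (camera adjusted p = 0.776), CCL5 by 0.50 and CXCL10 by 0.37, the latter with an edgeR adjusted p of 0.0198 that became 0.0967 without GFP replicate 3, 0.0511 without GFP replicate 1 and 0.0657 without CTRB1 replicate 2. Of 14 TGF-beta and BMP genes, 4 were higher, INHBE included, and 2 were lower (camera adjusted p = 0.361). Of 13 Wnt genes, 2 were higher (1 adjusted over the list alone; camera adjusted p = 0.829), and of 13 Notch genes 2 were higher, HES4 by 0.23 and HEY1 by 0.13 (camera adjusted p = 0.869). Of 22 genes linked to cell competition, 4 were higher and 7 lower (camera adjusted p = 0.361), with FLNA, an actin crosslinker gene, at -0.43 and the polarity gene SCRIB at -0.14. Of 22 extracellular matrix genes, 6 were higher and 2 lower (camera adjusted p = 0.869), and of 17 mesenchymal genes 4 were higher and 1, VIM, was lower (camera adjusted p = 0.911). Of 11 epithelial junction and keratin genes, 1, DSP, was lower (log2 change -0.12; camera adjusted p = 0.869). Of 19 antigen presentation genes, 2 were higher and 6 lower (camera adjusted p = 0.361), with B2M at -0.23 and HLA-DRB1 at -0.55.

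Of 6 neuronal genes that HEK293 cells express, 1 was higher and 2 lower (3 lower adjusted over the list alone; camera adjusted p = 0.547), with UCHL1 at -0.18. Markers of other cell types lay mostly below the expression filter, with only 2 fibroblast, 2 blood, 1 endothelial and 2 keratinocyte markers past the expression filter, too few for set tests. The fibroblast markers ACTA2 and COL1A1 were higher (log2 changes 0.55 and 0.23), the blood marker HBA1 and the endothelial marker ESAM were lower (-0.54 and -0.48), and the keratinocyte markers GJB2 and SFN did not pass (edgeR adjusted p = 0.193 and 0.326). ACTA2, HBA1 and ESAM lay at 5 CPM or less in both groups. Each of the 4 calls was lost on leaving out at least 1 library, with a highest edgeR adjusted p of 0.0539 for ACTA2 (without GFP replicate 3), 0.12 for COL1A1 (without CTRB1 replicate 2), 0.107 for HBA1 (without GFP replicate 3) and 0.0867 for ESAM (without GFP replicate 3).

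**Figure D3:**
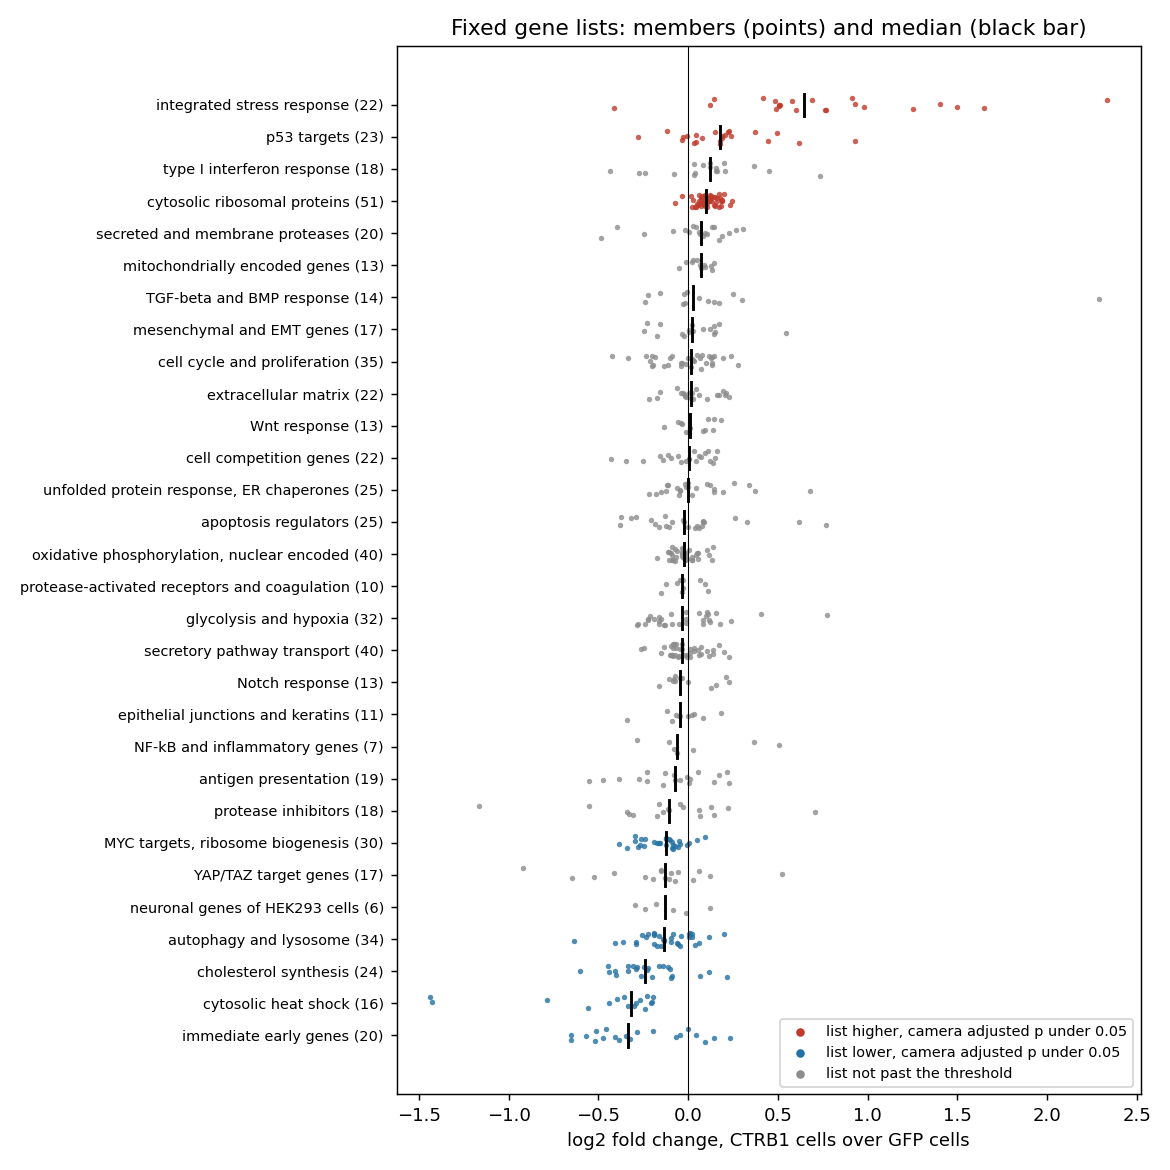
Each point is the log2 fold change of CTRB1 cells over GFP cells (x) of 1 gene in 1 of the 30 tested lists (y, with the number of measured genes in parentheses), and each black bar is the median of its list. Red lists were higher and blue lists lower at a camera adjusted p under 0.05, and grey lists did not pass. The integrated stress response has the highest median (0.645), and immediate early genes (-0.334) and cytosolic heat shock genes (-0.321) have the lowest.

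In all, 30 of 35 lists had enough measured genes to be tested, and 3 passed as higher and 5 as lower with camera at a preset correlation. With an estimated correlation 4 calls held, those of the integrated stress response, heat shock, cholesterol synthesis and ribosome biogenesis lists. Where no count adjusted over the list alone is given, it was the same as over all genes tested. The median, mean and direction of the set test differed in sign for cell cycle (median 0.018, mean -0.018), apoptosis (-0.021, 0.001), NF-kB (-0.065, 0.052), secreted proteases (0.073, 0.034, tested as lower), cell competition (0.005, -0.03) and Notch genes (-0.044, 0.005), none of which passed. The authors' deposited table marks 336 genes as up and 257 as down, all with an absolute log2 fold change of at least 0.501. Their unadjusted p in that table reaches 0.0498 and their adjusted p 0.127, so the marks do not follow an adjusted p of 0.05. Among genes called by edgeR, 195 higher and 83 lower had a log2 change of at least 0.5 in size. The adjusted p in the authors' table is under 0.05 for 4335 genes. Of the 4197 of these 4335 tested here, 4130 were called in the same direction by edgeR. Both comparisons describe the same 6 libraries, so this overlap is not independent support.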

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

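Running limma on log2(FPKM + 1) beside edgeR, thinning, the GC and length offset and the p53 list without SESN2 were added after the data were seen. Under the alternatives run on the whole table, the count of called genes stayed between 3229 and 4665 (4479 here), except 2949 with limma on quantile-normalized FPKM and 2891 with limma without trend or robust moderation, and the cause was not tested. DESeq2 called 4480 genes (5 had no adjusted p), of which 4295 were also called here. Of the 4479 calls, limma on log2(FPKM + 1) kept 66.9% in the same direction. Limma kept 59% with quantile normalization and 59.7% without trend or robust moderation. Against 2221 here, the number of higher genes was 1292 with limma on log2(FPKM + 1). It was 1289 and 1294 with pseudocounts of 0.1 and 5, and 1342 with FPKM rescaled to a common sum. Median-of-ratios scaling gave 1529, quantile normalization 1368, and limma without trend or robust moderation 1197. The numbers with a log2 change of at least 1 (29 higher and 13 lower) were 63 and 91 with no expression filter, which tests more low genes, and 15 and 4 with a mean FPKM of at least 5, which tests fewer. They were 14 and 3 with limma on log2(FPKM + 1) and with median-of-ratios scaling, 7 and 2 with a pseudocount of 5, which shrinks the change of low genes, 15 and 3 with quantile normalization, 17 and 5 with FPKM rescaled to a common sum, and 16 and 4 without trend or robust moderation.

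Leaving out 1 library gave 3334 to 4390 called genes, 1605 to 2134 higher and 1728 to 2256 lower, 27 to 33 and 11 to 18 with a log2 change of at least 1, and 8 to 9 lists past the threshold; CTRB1 stayed at a log2 change of 14.49 to 15.89. Of 125 called genes named by the rule, 17 lost the call without some library (edgeR adjusted p 0.0502 to 0.161). The lists of the integrated stress response and of heat shock kept their direction and their call in every alternative with a list test (DESeq2 has none), with medians of 0.53 to 0.66 and -0.34 to -0.28. With an estimated correlation 4 lists passed, 1 higher and 3 lower, and fry, which does not compare a list with other genes, called 20, 8 higher and 12 lower.

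The log2 change of ATP5MC3 reversed from -0.17 to 0.1014 with limma on log2(FPKM + 1) and without trend or robust moderation, 0.1024 and 0.0974 with pseudocounts of 0.1 and 5, 0.1183 with median-of-ratios scaling, 0.1578 with quantile normalization and 0.1069 with FPKM rescaled to a common sum. Its ratio of count to FPKM differed 1.32-fold between libraries, so the reversal comes with the change of unit. With quantile normalization ATP5PB reversed to 0.0133 and MT-ATP8 to -0.0153, and the cause was not tested. The replicate number as a block gave 4320 calls, and same-numbered libraries had correlations of -0.042, 0.101 and -0.177 in their deviations from the group means, where GFP replicate 1 correlated best with CTRB1 replicate 3, so the numbers were not taken to pair samples. Depth limits the number of calls, since thinning every library to the smallest total left 4064 calls, 3911 of them among the 4479.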

Other observations

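The gene groups of the next paragraph, the tests on CTRB2, thinning and the GC and length offset were chosen only after the results they bear on were seen.

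Single genes of amino acid supply and tRNA charging were counted without a set test. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 13 were higher, 4 were lower and 3 did not pass in edgeR's test, with a median log2 change of 0.228. CARS1 rose by 0.67 ± 0.0287 (SE), GARS1 by 0.64 ± 0.0226 and SARS1 by 0.53 ± 0.0297, while RARS1 had a log2 change of -0.29. Of 17 genes of serine, glycine and one-carbon metabolism, 8 were higher, 2 were lower and 7 did not pass, with ALDH1L2 at 1.05, and of 18 amino acid transporters 11 were higher, 1 was lower and 6 did not pass, with SLC6A9 at 1.30 and SLC1A4 at 0.98. MTHFD2, PHGDH, PSAT1, SHMT2, SLC7A5, SLC7A11 and SLC3A2, all among the higher genes, are also members of the integrated stress response list. Of 17 mitochondrial synthetase genes, 3 were higher and 3 lower. A hypothesis is that the rise may cover all synthetase genes, mitochondrial ones included. It required most mitochondrial genes to be called higher, which was not so. Their median of 0.003 had an upper 95% bootstrap bound of 0.109, above the bound of 0.1 set for excluding it. The value of 0.109 lies under the cytosolic median of 0.228 (95% bootstrap interval 0.01 to 0.434). These bounds come from resampling genes and not libraries, and the cytosolic genes were picked after their rises were seen. The comparison therefore cannot decide how large a mitochondrial rise could be. It shows only a lower median than that of the picked cytosolic genes, and a small mitochondrial rise stays open.

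The integrated stress response list was higher and the heat shock list lower in CTRB1 cells. GC or length bias is argued against, since the medians of these lists kept 100.5% and 102.3% of their values with the offset. After thinning every library to one total the medians kept 101.7% and 100.4%. Random thinning keeps the expected ratios between libraries, so these values could hardly have differed. Thinning therefore cannot decide on differences that go with depth, and every GFP library was deeper than every CTRB1 library. A lower temperature of the CTRB1 cultures before lysis could lower heat shock genes. It was required that the cold-inducible genes RBM3 and CIRBP both rise by at least 0.2. The value of CIRBP, a rise of 0.47, had been seen when this was set, and that of RBM3 had not. RBM3 had a log2 change of -0.0011 ± 0.0211 (SE), so the requirement was not met. As the 2 genes disagree, a temperature difference is not excluded. A general unfolded protein response could raise ATF4 targets. The chaperone list had a median of 0.001 with an upper 95% bound of 0.121, where a median of at least 0.2 was required. It did not pass with camera (adjusted p = 0.677), while fry called it higher (adjusted p = 0.0484). Its members moved both ways, with 7 higher and 6 lower, so a small rise cannot be told apart here. A response to CTRB1 itself and a difference in medium, density or harvest day between the groups, which the design confounds, both stay open and untested.

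CTRB2 rose with CTRB1. A pancreatic acinar programme is argued against, because none of the 30 other acinar genes of the list in the table came near the level of CTRB2 in CTRB1 cells. The highest, BHLHA15, had a mean FPKM of 1.82 there and 1.83 in GFP cells, 0.87% of the 210.1 of CTRB2, where a bound of 5% had been set after the data were seen. In the CTRB1 libraries 18 of the 30 had no count, and without an expression filter 0 of the 19 that could be tested were called higher. Reads of introduced CTRB1 counted at CTRB2 may account for the signal, as the share of CTRB2 was the same in the 3 CTRB1 libraries within counting error (chi-square p = 0.74) and both coding sequences share long identical stretches. Genuine CTRB2 transcription at a fixed ratio to CTRB1 would give the same shares and stays open.

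The larger changes outside the stress lists, such as that of LYPD1, might come from copy-number differences between both lines. Across windows of 50 neighbouring expressed genes, the most extreme median log2 change was -0.1259, on chromosome 1 from 36185819 to 40783488 in the table's coordinates. A copy-number change was set to need more than 0.2, and the largest of 1000 shuffles of gene order reached 0.1427. The 95% quantile of the shuffles' largest medians was 0.1135. This window and windows on chromosome 19 (-0.1181 and -0.1168) passed that quantile in size, so small regional shifts stay open. Gains or losses of single genes were not tested by these windows and stay open, as does a biological effect of CTRB1.

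Among the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 4479 genes, and the highest of the others called 2. With 10 splits the share cannot fall under 0.05.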
